A study of Mus musculus with 2 samples.

How the data were processed

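RNA from primary mouse glia (strain C57BL/6J) was measured on 2 Agilent 2-colour arrays, each of which held oligodendrocyte RNA and astrocyte RNA in competition. Per the labels' protocols, oligodendrocytes were shaken off mixed glial cultures, the remaining cells were kept in serum-containing medium, microglia were then shaken off, and the astrocytes left on the dish were harvested with trypsin. Total RNA was extracted with Trizol and amplified linearly with an Agilent low-input kit, per the labels' protocols. The labels put astrocytes in Cy3 and oligodendrocytes in Cy5 on the array of replicate 1, and the reverse on the array of replicate 4. The series text speaks of more independent samples per cell type than these; other arrays were not analysed here. The labels number the replicates separately without saying whether they came from separate cultures, so p-values measure only the spread between these 2 arrays, which may be technical.

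The deposited scanner files hold spot intensities in each channel, read with Agilent Feature Extraction, per the file headers. The mean signal and local background intensity used here were not normalised by the authors. The deposited log10 ratios of Cy5 over Cy3 were background-subtracted and dye-normalised by Feature Extraction, per the file headers, with low signals replaced by surrogate values. The authors' value table held the same log10 ratios, with a largest difference of 0 from the scanner files, a median of 0 on each array and the dye swap not turned. The headers name mm7 as the genome build of the array design, and probe coordinates are given as the files list them; a few of them span more than the probe itself. Both arrays carry the same slide and scan in their headers, so neither could be tested as a batch.

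Each array had 45018 spots, of which 1639 were controls and 43379 read genes. Spots were well above background for 83.9% (oligodendrocyte) and 78.5% (astrocyte) of gene spots on replicate 1, and for 76.6% and 81.3% on replicate 4. None were saturated. The number of arrays limits the precision: each gene has 1 residual degree of freedom, and most of its variance estimate was borrowed from other genes.

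Background was corrected with normexp and an offset of 50 in limma 3.58.1 (R 4.3.3). Ratios were then normalised by loess within each array with control spots at weight 0, turned to oligodendrocyte over astrocyte, and averaged over spots of a probe. The offset pulls ratios of dim probes toward 0. A probe entered if it was well above background in 1 cell type on both arrays and had no spot marked as an outlier by Feature Extraction. Of 41174 gene probes, 152 carried such a mark and 32565 entered, which gave 21896 genes. A gene was represented by its brightest entering probe. Names came from RefSeq tables of the GRCm38.p6 assembly: 24913 gene spots matched by accession, 6857 by symbol and 3127 by an older name, and 8482 kept the name in the file. Of 7337 genes with several entering probes, 34 had probes that differed from 0 by at least 0.5 in opposite directions.

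Genes were tested with limma's lmFit and eBayes against a log2 ratio of 0, and called at a Benjamini-Hochberg adjusted p under 0.05. Values are means over the 2 arrays with their SD. Where a gene was not well above background in 1 cell type on both arrays, the fold compares the bright cell type's mean signal with a floor. On each array this floor was the higher of the dim probe's own signal and the lowest signal among probes well above background. Channels were normalised by loess and then Aquantile. Where the dim probe's own signal was the higher, the fold is the mean fold and not a lower bound. A 2-fold change on both arrays was counted separately, without a test. The 17 gene lists were compared with all other genes by limma's camera with a preset correlation of 0.01, and again with an estimated correlation. The latter has only 1 residual degree of freedom and gave no adjusted p below 0.285. Limma's fry, also planned, tested the genes of each list against a log2 ratio of 0 rather than against other genes. Of 497 list genes, 3 had no probe.

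Before the data were examined, the lists, the tests, the alternatives and the rule for named genes were fixed. The rule took the 8 largest called ratios per direction among genes well above background in every channel. It also took the 4 brightest per direction among called genes well above background in 1 cell type only. To these it added the 3 largest called ratios of each list, and a set of genes named in advance. Other genes are named where a count was 5 or fewer or where a group needed an example, and were chosen after their values were seen. Alternatives were no background subtraction, an offset of 10, Feature Extraction's log ratio, the authors' value table, median centring, scaling between arrays, no filter or a stricter filter on dim probes, marked spots kept, the mean of a gene's probes, a trended robust prior, limma's treat against 0.5, a fit of separate channels, and each array alone. Scaling on the spike-in probes, and further gene lists, were chosen after seeing the data.

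The steps were tested on simulated data with the 21896 genes and the spread of these arrays, in which 100 genes changed 2-fold and 100 changed 4-fold. The simulated comparison recovered 74% of the 2-fold and 100% of the 4-fold genes, with median log2 estimates of 0.89 and 1.80, and 1 of 175 calls was false. Far fewer genes changed in it than the 41.2% called in the data, equally in both directions, and its noise came from the fitted variance model. It therefore tests neither loess with many changed genes nor that variance model. A planned test of miR-17~92 seed sites in 3' untranslated regions was not run, because no transcript sequences were used here. Results for some genes of the rule and the lists are not reported here; they remain in the counts and medians.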

Results

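The messenger RNA of cultured mouse oligodendrocytes, the cells that make myelin, was compared with that of cultured astrocytes. The series asks which mRNAs are enriched in oligodendrocytes, in a study of the miR-17~92 family of microRNA clusters. Each of 2 arrays held both cell types, with the dyes exchanged between the arrays of replicate 1 and replicate 4. Of 21896 genes tested, 20445 (93.4%) were well above background in both cell types on both arrays, 193 only in oligodendrocytes and 165 only in astrocytes. Before the dye swap was turned, the log2 ratios of the arrays correlated at a Pearson r of -0.93 and a Spearman rho of -0.81 across genes, which are not independent replicates; after turning, the values were 0.93 and 0.81. Over 137 probes printed several times, the median difference between the arrays was 0.168 in log2, against 0.0137 from the spot-to-spot spread; the count of 2 replicates comes from the labels, since any separate hybridisations would differ by more than spots do.

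Myelin genes were among those with the largest ratios toward oligodendrocytes. Cldn11, a tight junction protein of myelin, was 41.9-fold higher, with a log2 ratio of 5.39 ± 0.26 (SD, n = 2), and Ugt8a, which makes the myelin lipid galactocerebroside, stood at 4.69 ± 0.20. On the astrocyte side, Itih3, an inter-alpha-trypsin inhibitor chain, was higher in astrocytes at a log2 ratio of -4.64 ± 0.12, and Gfap, the astrocyte intermediate filament, was 16.6-fold higher (-4.05 ± 0.22) on its brightest probe. The other probes of Gfap read -2.66 and -3.06. In all, limma called 9014 genes (41.2%), 4061 higher in oligodendrocytes and 4953 higher in astrocytes. Over all genes tested, 76.3% had the same sign on both arrays; all 9014 called genes did, which the call itself nearly ensures.

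At least 2-fold on both arrays, with no test, were 2724 genes, 1117 higher in oligodendrocytes and 1607 higher in astrocytes, and all 2724 were also called. With median centring in place of loess, limma called 2928 genes, 1085 higher in oligodendrocytes and 1843 in astrocytes, and with Feature Extraction's log ratio 4030 genes were at least 2-fold different on both arrays, 1770 higher in oligodendrocytes and 2260 in astrocytes. The split between directions rests on the loess step, which sets the typical gene to a ratio near 1. The spike-in probes read 0.69 higher in log2 on the oligodendrocyte side of the arrays. With ratios set to the spike-ins, a scaling chosen after seeing the data, every log2 ratio moves by that amount toward astrocytes and the split of called genes became 1335 (6.86%) to 18115, in place of 4061 (45.1%) to 4953. Directions are otherwise given relative to the typical gene.

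**Figure D1:**
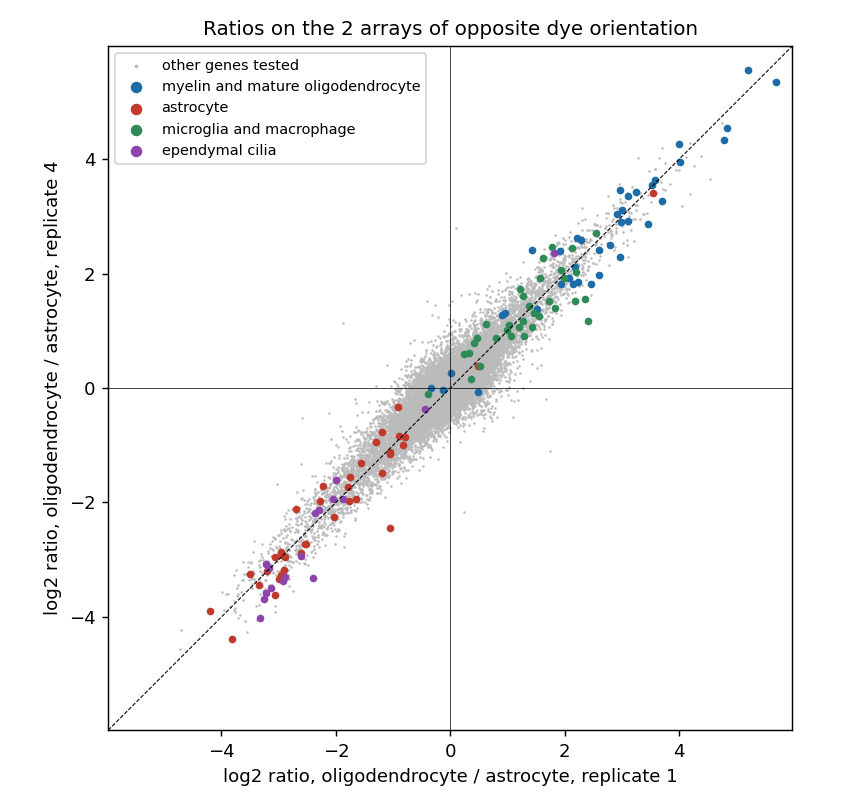
The log2 ratio of oligodendrocyte over astrocyte RNA on replicate 1 (horizontal) and replicate 4 (vertical), 1 point per gene of the 21896 tested, with members of 4 gene lists in colour and the line of equality dashed. Myelin and microglia genes lie mostly at the upper right and astrocyte and ependymal cilia genes at the lower left, at a Pearson r of 0.93 across genes; spike-in scaling would move every point by 0.69 toward the lower left.

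Other genes with large called ratios toward oligodendrocytes were Dct, Kcna1, Bcas1, Dgat2 and Tppp. Dct, the enzyme dopachrome tautomerase of melanin synthesis, was 45.4-fold higher (5.50 ± 0.19). Kcna1, a voltage-gated potassium channel, stood at 4.70 ± 0.078, and Bcas1, a gene of early myelinating oligodendrocytes, at 4.57 ± 0.31. Dgat2, an enzyme of triglyceride synthesis, reached 4.25 ± 0.065 and Tppp, a tubulin polymerisation protein, 4.22 ± 0.23. The largest limma adjusted p among these genes, Cldn11 and Ugt8a included, was 7.01e-08. In mm7, the probe of Dct lay on chromosome 14 from 112415582 to 112415642 and that of Cldn11 on chromosome 3 from 30976006 to 30976065; whether they fall in a coding exon or an untranslated region was not examined here.

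Toward astrocytes, Itih3 was followed by Cfi, complement factor I, at -4.47 ± 0.34, and Mlc1, a membrane protein of astrocyte end feet, at -4.10 ± 0.41. After Gfap came Kcne1l, a potassium channel subunit, at -3.92 ± 0.054, and the protease inhibitor A2m at -3.91 ± 0.51. Armc3 stood at -3.87 ± 0.22 and Maats1, a gene of motile cilia, at -3.84 ± 0.0075, although a dimmer probe of Maats1 read -1.17. The largest limma adjusted p among these 8 genes was 1.19e-07, for A2m. The mm7 position of the Itih3 probe was chromosome 14 from 28338399 to 28338458, that of Cfi chromosome 3 from 129714547 to 129714606, and that of Gfap chromosome 11 from 102999540 to 102999599.

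Some called genes were not well above background in 1 of the cell types. Cyp1a1, a cytochrome that metabolises aromatic hydrocarbons, was at least 4.29-fold higher in oligodendrocytes and Klhl4 at least 2.73-fold. Pkd2l1 stood 2.31-fold higher and Pira1 2.26-fold. In astrocytes, Lrriq1 stood 4.51-fold higher, Map3k19 3.12-fold, the organic anion transporter Slco1a1 3.11-fold, and the defensin Defb1 3.04-fold. For all but Cyp1a1 and Klhl4 the dim probe's own signal set the value, which is then the mean fold and not a lower bound. Slco1a1, for example, had a log2 ratio of -1.39 on replicate 4, and its other probe read -0.47. The largest limma adjusted p of these 8 genes was 4.72e-05, for Pkd2l1.

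Genes of myelin and mature oligodendrocytes moved together toward oligodendrocytes. Of 38 tested, 34 were higher in oligodendrocytes, with a list median of 2.57 (5.93-fold). The other 4, not called, were Myrf at 0.21, Cryab at 0.14, Ndrg1 at -0.078 and Plekhb1 at -0.17. Adjusted over the list alone, 34 were called; limma's camera gave an adjusted p = 1.64e-24, against an adjusted p = 0.285 with an estimated correlation. Mbp, the myelin basic protein, stood at 3.17 ± 0.42 and Mog, a glycoprotein of the outer myelin surface, at 3.05 ± 0.080, although a dimmer probe of Mog read 0.95. Another probe of Mbp, nearly as bright, read 2.11. The third and dimmest probe of Ugt8a read 0.43. Microglia and macrophage genes, with a median of 1.39, were also higher on this side.

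Genes of precursors and lineage factors split more. Among 28 tested, 20 were higher in oligodendrocytes and 5 higher in astrocytes, with a median of 0.95, and 26 were called when adjusted over the list alone. The camera adjusted p in limma was 8.68e-07, and the adjusted p = 0.31 with an estimated correlation. Gpr17, a receptor of committed precursors, reached 3.79 ± 0.56 on its brightest probe and 0.19 on its other probe, a dim one whose ratio the offset pulls toward 0. The transcription factor Zfp536 stood at 3.36 ± 0.073, Sox10 at 2.54 ± 0.020 and Olig2 at 1.02 ± 0.051, while the median-centred value of Olig2 (0.91) was not called (limma adjusted p = 0.132; over all alternatives, 6.56e-09 to 0.132). Pdgfra, the growth factor receptor of precursors, stood at 0.51 ± 0.22 on a dim probe, at 2.20 on a brighter probe left out for a marked spot, and at -0.18 with spike-in scaling; its call was lost with median centring (limma adjusted p = 0.389, in a range of 1.15e-07 to 0.389 over the alternatives). Microglia genes, with a median of 1.39, moved the same way as this list. The 5 genes higher in astrocytes were Lnx1 (-1.90), C1ql1 (-0.83), Sox5 (-0.76), Sox6 (-0.45) and Rgcc (-0.35); Ptprz1 (0.18) and Cacng4 (0.20) were not called.

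Cholesterol biosynthesis genes were mostly higher in oligodendrocytes. Of 25 tested, 18 were higher in oligodendrocytes and 7 were not called, with a median of 0.84 and 18 called when adjusted over the list alone. The limma camera adjusted p was 5.02e-08, and the adjusted p = 0.285 with an estimated correlation. Hsd17b7 stood at 2.99 ± 0.072, and lanosterol synthase Lss at 2.20 ± 0.34. Dhcr7, the last enzyme of the pathway, stood at 1.68 ± 0.10. With spike-in scaling the list median was 0.15; the median of microglia genes, as reported, was 1.39.

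Astrocyte genes moved together toward astrocytes. Of 37 tested, 35 were higher in astrocytes, with a median of -2.13 (4.36-fold), and all 37 were called when adjusted over the list alone. The water channel Aqp4 stood at -3.40 ± 0.067, the glutamate transporter Slc1a3 at -3.04 ± 0.19 and Aldh1l1, an enzyme of folate metabolism, at -2.93 ± 0.0095. The 2 genes on the other side were S100b, a calcium-binding protein that oligodendrocyte lineage cells also make, at 3.48 ± 0.10, and the glypican Gpc5. Gpc5 was 1.34-fold higher against the floor for dim probes and not well above background in astrocytes. In limma's camera the list had an adjusted p = 2.17e-18, against an adjusted p = 0.285 with an estimated correlation. Ependymal cilia genes, with a median of -2.87, were higher on the same side.

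Genes of reactive astrocytes were also higher in astrocytes. Among 27 tested, 21 were higher in astrocytes and 3 in oligodendrocytes, with a median of -1.63 beside one of -2.87 for ependymal cilia genes, and 24 were called when adjusted over the list alone. The limma camera adjusted p was 4.59e-09, and the adjusted p = 0.285 with an estimated correlation. Complement C3 stood at -3.33 ± 0.23, Tm4sf1 at -3.31 ± 0.20 and the cytokine receptor Osmr at -3.14 ± 0.19. The 3 on the other side were Ptgs2 (1.10), Cd14 (0.67), which microglia also make, and Sphk1 (0.49); Slc10a6 (-0.062), Fbln5 (-0.10) and S100a10 (-0.25) were not called.

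Genes of motile ependymal cilia had the largest list median toward astrocytes. Of 17 tested, 16 were higher in astrocytes, with a median of -2.87 (7.29-fold), and 17 were called when adjusted over the list alone. Ak7, an adenylate kinase of cilia, stood at -3.67 ± 0.49 and its mean over probes at -2.16; Dynlrb2, a dynein light chain, stood at -3.47 ± 0.30 and Cfap126 at -3.40 ± 0.26. Ttr, the thyroxine carrier of the choroid plexus, stood on the other side at 2.09 ± 0.39. The camera adjusted p in limma was 3.18e-11, and the adjusted p = 0.285 with an estimated correlation.

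Interferon and antigen presentation genes were higher in astrocytes or not called. Of 26 tested, 15 were higher in astrocytes and 11 were not called, with a median of -0.49 and 15 called when adjusted over the list alone. Ifi44 stood at -2.65 ± 0.33, Ifit1 at -1.83 ± 0.40 and Ifit3 at -1.80 ± 0.044, all genes induced by interferon. Ependymal cilia genes (median -2.87) were higher on the same side and microglia genes (median 1.39) on the other. The limma camera adjusted p was 2.37e-05, and the adjusted p = 0.31 with an estimated correlation.

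Serum response and actomyosin genes were more often higher in astrocytes. Among 28 tested, 17 were higher in astrocytes, 3 in oligodendrocytes and 8 not called, with a median of -0.76 (-2.87 for ependymal cilia genes) and 20 called when adjusted over the list alone. The myosin light chain Myl9 stood at -2.25 ± 0.61, Tagln at -2.10 ± 0.37 and the calponin Cnn1 at -1.92 ± 0.17. Tpm2 (0.92) and Fhl2 (0.46) were among those on the other side. The camera adjusted p in limma was 0.000361, and the adjusted p = 0.31 with an estimated correlation. With spike-in scaling and a preset correlation the limma camera adjusted p was 0.0744, in a range of 7.78e-05 to 0.0744 over the alternatives with a preset correlation. That scaling lowers all genes alike, so the list's difference from other genes in log2 ratio stayed the same.

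BMP and Notch response genes went both ways. Of 27 tested, 16 were higher in astrocytes and 8 in oligodendrocytes, with a median of -0.62 (-2.87 for ependymal cilia genes) and 24 called when adjusted over the list alone. The BMP-induced regulator Id4 stood at -3.40 ± 0.10 and Hey1, a Notch target, at -2.39 ± 0.028, while Smad7, an inhibitor of the same family of receptors, was at 1.87 ± 0.032. Hes6 (0.053), Bmp7 (-0.059) and Jag2 (-0.31) were not called. The limma camera adjusted p was 0.0458, and the adjusted p = 0.496 with an estimated correlation. The adjusted p was 0.0521 without background subtraction, within a range of 0.00687 to 0.91 over the limma alternatives with a preset correlation.

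**Figure D2:**
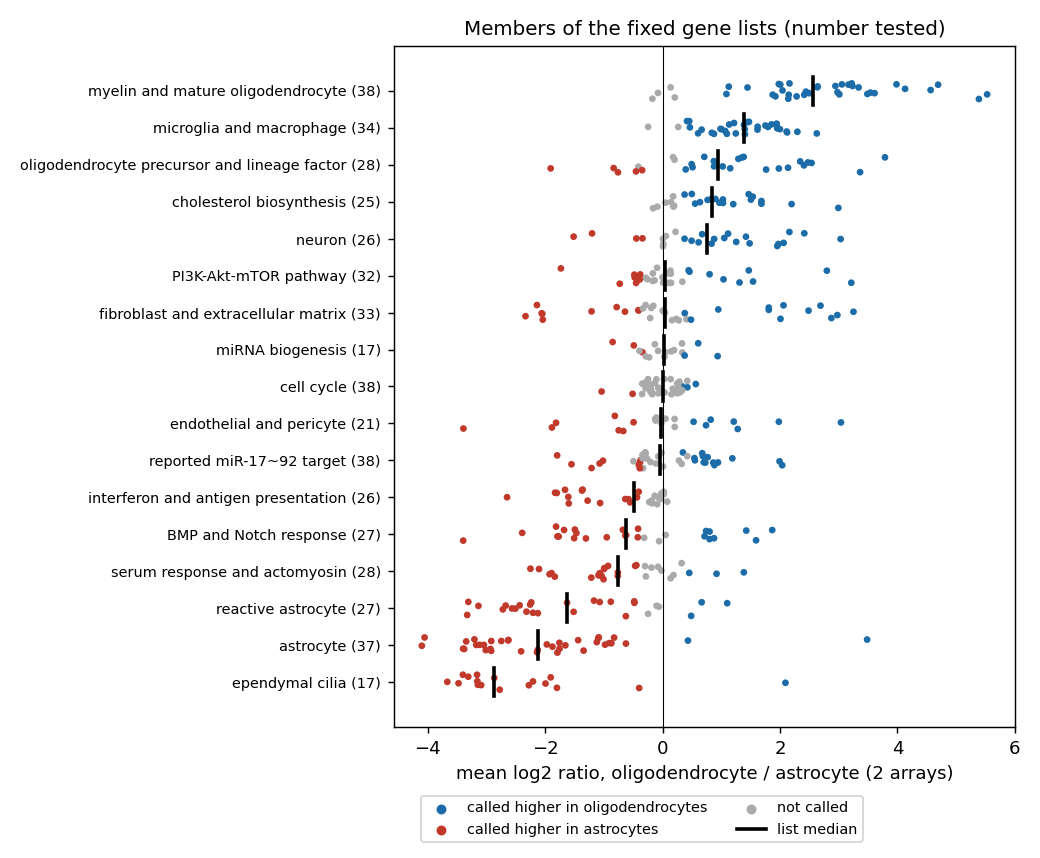
Mean log2 ratio of oligodendrocyte over astrocyte RNA over 2 arrays (horizontal) for each tested member of 17 gene lists (listed with the number tested), coloured by its call, with a black bar at the list median. Medians ran from -2.87 for ependymal cilia to 2.57 for myelin; with spike-in scaling every point moves left by 0.69, and the medians of the fibroblast, cell cycle, PI3K-Akt-mTOR and miRNA biogenesis lists fall below 0.

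Markers of some other cell types differed between the cultures. Of 34 microglia and macrophage genes tested, 32 were higher in oligodendrocyte cultures, with a median of 1.39 (2.63-fold), and 32 were called when adjusted over the list alone. The phagocyte receptor Trem2 stood at 2.63 ± 0.11, the chemokine Ccl4 at 2.30 ± 0.23 and the leukocyte phosphatase Ptprc at 2.12 ± 0.49, while Cx3cr1 stood at 1.22 ± 0.072 and Aif1 at 0.99 ± 0.10. Aif1 was not called with median centring (limma adjusted p = 0.131, in a range of 2.86e-08 to 0.131 over the alternatives). Itgam (0.27 ± 0.14) and Fcgr2b (-0.25 ± 0.20) were not called; with spike-in scaling Itgam stood at -0.42 and was called higher in astrocytes (limma adjusted p = 0.0089, in a range of 0.0089 to 1 over the alternatives). The camera adjusted p in limma was 5.51e-16, and the adjusted p = 0.285 with an estimated correlation.

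Neuronal genes were higher in oligodendrocyte cultures as well. Among 26 tested, 17 were higher in oligodendrocytes and 4 in astrocytes, with a median of 0.75 (1.39 for microglia genes) and 21 called when adjusted over the list alone. Elavl3, an RNA-binding protein of neurons, stood at 3.03 ± 0.17, although its other probe, a dim one, read 0.098. The vesicular GABA transporter Slc32a1 stood at 2.41 ± 0.25, Gad2, an enzyme of GABA synthesis, at 2.16 ± 0.023, and the synaptic protein Snap25 at 1.95 ± 0.16. Camk2a (-1.51), Stmn2 (-1.20), Gap43 (-0.45) and Dlx2 (-0.34) were higher in astrocytes. The limma camera adjusted p was 1.47e-05, and the adjusted p = 0.327 with an estimated correlation; with spike-in scaling the median was 0.066.

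Endothelial, pericyte and fibroblast genes showed no common direction. Of 21 endothelial and pericyte genes, 7 were higher in oligodendrocytes, 7 in astrocytes and 7 not called, with 14 called when adjusted over the list alone. Their median was -0.022 and their mean -0.0054, while the camera test in limma, with an adjusted p = 0.752, pointed up; median centring turned the median to 0.065, and it was -0.060 on replicate 1 and 0.023 on replicate 4. Anpep, an aminopeptidase, stood at 3.04 ± 0.083, the proteoglycan Cspg4, also made by oligodendrocyte precursors, at 1.98 ± 0.10, and the transporter Slco1a4 at -3.39 ± 0.14. Of 33 fibroblast and matrix genes, 12 were higher in oligodendrocytes and 10 in astrocytes, with 24 called when adjusted over the list alone. Their median was 0.040, and -0.65 with spike-in scaling (limma camera adjusted p = 0.37; 0.000899 with spike-in scaling and 0.0402 with an offset of 10, in a range of 0.000899 to 0.566 over the alternatives with a preset correlation). As reported, camera pointed up for this list, toward oligodendrocytes, and the list mean was 0.29. Camera compares a list with other genes, and spike-in scaling lowers all genes alike. Its adjusted p with that scaling is therefore not evidence of matrix genes higher in astrocytes. Lox, an enzyme that crosslinks collagen, stood at 2.98 ± 0.16 and Mgp at 2.88 ± 0.21. Postn stood at 3.25 ± 0.22 on its brightest probe and 0.16 on its other, dim probe, and Col1a1 at 2.69 ± 0.25 with further, dimmer probes at 1.67 and 0.39.

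Reported targets of the miR-17~92 family went in both directions. Of 38 tested, 14 were higher in oligodendrocytes, 9 in astrocytes and 15 not called, with 28 called when adjusted over the list alone. The median was -0.044, the mean 0.079 and the limma camera test pointed up with an adjusted p = 0.547; the median was 0.0015 with Feature Extraction's log ratio. Cdkn1c, an inhibitor of cell cycle kinases, stood at 2.04 ± 0.052, the ubiquitin ligase Mylip at 1.99 ± 0.38 with a dimmer probe at 0.45, and the cytokine inhibitor Socs3 at -1.79 ± 0.13. The death-promoting Bcl2l11 stood at 0.77 ± 0.095 and Cdkn1a at 0.68 ± 0.21, or 0.079 and -0.013 with spike-in scaling. Neither was called with spike-in scaling or median centring, with limma adjusted p from 1.04e-05 to 0.544 for Bcl2l11 and from 0.000191 to 0.924 for Cdkn1a over the alternatives.

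Genes of the PI3K-Akt-mTOR pathway and of microRNA biogenesis showed no common direction either. Of 32 pathway genes, 9 were higher in oligodendrocytes, 8 in astrocytes and 15 not called, with 18 called when adjusted over the list alone. Their median was 0.041, and -0.65 with spike-in scaling, -0.068 with median centring and -0.023 for the mean of probes (limma camera adjusted p = 0.344). It was -0.070 on replicate 1 and 0.14 on replicate 4. Igf1, a growth factor that microglia also make, stood at 3.21 ± 0.011, the regulatory subunit Pik3r3 at 2.80 ± 0.41 and the transcription factor Foxo1 at -1.73 ± 0.36. Of 17 biogenesis genes, Dicer1 (0.94 ± 0.13), Ago3 (0.61 ± 0.069, and -0.082 with spike-in scaling) and Tarbp2 (0.38) were higher in oligodendrocytes, and Drosha (-0.85 ± 0.12), Prkra (-0.49) and Tnrc6b (-0.34) in astrocytes. Adjusted over the list alone, 5 of the 17 were called; the list median was 0.032, and -0.66 with spike-in scaling, -0.020 with median centring and -0.0045 with Feature Extraction's log ratio (limma camera adjusted p = 0.752). Dicer1 and Drosha cleave microRNA precursors; with median centring neither they nor Ago3 were called (limma adjusted p = 0.189, 0.133 and 0.536), in ranges of 3.76e-08 to 0.189, 3.25e-06 to 0.133 and 3.46e-05 to 0.536 over the alternatives. With spike-in scaling Dicer1 (0.25) and Ago3 were not called.

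Few cell cycle genes differed. Of 38 tested, 33 were not called and 2 were called when adjusted over the list alone. Pcna, the clamp of DNA polymerase (0.57 ± 0.64, and -0.12 with spike-in scaling), Ccne2 (0.42) and Birc5 (0.33) were higher in oligodendrocytes, and the cyclins Ccnd2 (-1.04 ± 0.12) and Ccnb2 (-0.51 ± 0.085) in astrocytes. The call of Pcna (limma adjusted p = 0.0380) was lost under several alternatives, in a range of 0.00238 to 0.625, and that of Ccnb2 with median centring (limma adjusted p = 0.479, in a range of 1.56e-05 to 0.479). Mki67, a marker of dividing cells, stood at 0.26 ± 0.42 and was not called; with spike-in scaling it stood at -0.43 and was called higher in astrocytes (limma adjusted p = 0.0229, in a range of 0.0229 to 1 over the alternatives). The list median was 0.016, and -0.67 with spike-in scaling and -0.081 with median centring (limma camera adjusted p = 0.736). On single arrays it was -0.041 for replicate 1 and -0.0086 for replicate 4.

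**Figure D3:**
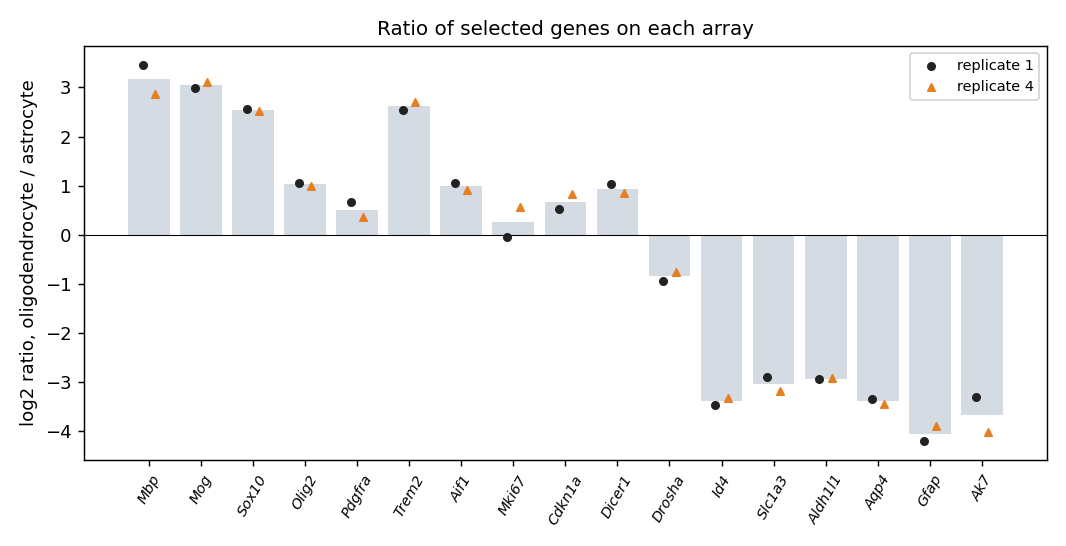
Log2 ratio of oligodendrocyte over astrocyte RNA (vertical) of selected genes, with bars from 0 to the mean of 2 arrays and symbols for each array. The ratios ran from 3.17 for Mbp to -4.05 for Gfap. With spike-in scaling the means of Pdgfra (-0.18), Mki67 (-0.43) and Cdkn1a (-0.013) fall below 0. Pdgfra is shown on a dim probe, since a brighter probe was left out for a marked spot.

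None of the 11 lists called by limma's camera with a preset correlation held its call with an estimated correlation. That test gave no unadjusted p below 0.0517, with 1 residual degree of freedom, so the losses do not show an effect of gene correlation. Its estimate lay below the preset 0.01 for some lists, such as myelin (-0.0242) and ependymal cilia (-0.0588). For others, such as precursors (0.0476), it lay above. Limma's fry kept the calls of these lists at an adjusted p of 0.0475 or lower, except serum response (0.0799) and BMP and Notch (0.0951). The smallest called ratio was 0.33 in log2 size, and the median SD of a gene over the arrays was 0.12. A fit of the unturned ratios, meant to count dye effects, called 0 genes in limma and 2 at an unadjusted p under 0.05, but its residual holds the cell-type difference, so it cannot show the absence of a dye effect. The mean dye ratio had a median size of 0.0868 in log2 and was at least 1 for 5 genes.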

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

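The tests in this part were all chosen after the spike-in values were seen. Probes for the added spike-in RNAs, which none of the comparisons use, read 0.69 ± 0.081 higher in log2 on the oligodendrocyte side (SD over 10 probes of 32 spots each), or 1.61-fold, in data outside the main measurement.

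The spike-in ratios of the unturned arrays correlated at 0.998 across probes, so the designed ratios followed the dye and cancel in the turned mean. A dye bias needs opposite signs on the arrays once turned, and the offsets given in the headers were 0.66 and 0.74, the smaller far above the spread of 0.081 between probes, which argues against it. A few abundant genes taking the oligodendrocyte signal would leave the summed gene signal per spike-in alike, but that sum was lower in oligodendrocytes by nearly as much as the typical gene, at -0.74 against -0.76. The offsets differed by only 0.080 between the arrays, which any cause that repeats in both labellings would give. Less mRNA per total RNA in oligodendrocytes may account for them, but a repeated unequal input of RNA or spike-in cannot be told apart from it. Other repeated differences between the samples were not tested, and the amounts added are not given in the sources used here. If oligodendrocytes did hold less mRNA per total RNA, the split of 1335 to 18115 genes with spike-in scaling would be nearer to transcripts per total RNA than that of 4061 to 4953.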

How the results depend on the processing

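Over 87 named genes and 12 alternatives, with the authors' value table left out as it repeats Feature Extraction's ratios, and without the stricter test and single arrays, 1008 of 1036 values kept their direction and side of the threshold, 22 lost their call and 6 turned. The number of called genes ran from 8526 to 9595 over the alternatives other than those below. The causes were not tested, except where stated. Median centring, which leaves an intensity-dependent dye curve in the ratios (the mean dye ratio had a median of 0.291), called 2928 genes, 1085 higher in oligodendrocytes and 1843 in astrocytes. A test against a log2 ratio of 0.5 in either direction called 3816, 1608 and 2208, as its stricter null implies. Without the replicate block, in separate channels that ignore the pairing within arrays, 9472 genes were called and, of the lists and named genes, only Pcna and the BMP and Notch list lost their calls (for the list, -0.62, limma adjusted p = 0.0589, in a range of 0.00687 to 0.91 over its alternatives with a preset correlation). Feature Extraction's log ratio and the authors' value table each gave 4030 genes at least 2-fold different, 1770 higher in oligodendrocytes and 2260 in astrocytes, and medians of 0.0015 for miR-17~92 targets and -0.0045 for miRNA biogenesis.

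Spike-in scaling, chosen after seeing the data, called 19450 genes, 1335 and 18115 by direction, with 4895 at least 2-fold on both arrays (427 and 4468). By construction it lowered every ratio. It turned the medians of the fibroblast (-0.65), cell cycle (-0.67), PI3K-Akt-mTOR (-0.65) and miRNA biogenesis (-0.66) lists. The ratios of Cdkn1a (-0.013), Ago3 (-0.082), Pcna (-0.12), Itgam (-0.42) and Mki67 (-0.43) also turned, as did that of Pdgfra (-0.18) on its dim probe. The serum response (-1.45) and BMP and Notch (-1.31) lists lost their calls (limma adjusted p = 0.0744 and 0.91). As all genes were lowered alike, these losses do not show a smaller difference in log2 ratio between the lists and other genes. Medians near 0 turned elsewhere too: with median centring for endothelial (0.065), cell cycle (-0.081), PI3K-Akt-mTOR (-0.068) and miRNA biogenesis (-0.020) genes, with either other filter on dim probes for endothelial genes (0.015), and with the mean of probes for PI3K-Akt-mTOR genes (-0.023). BMP and Notch genes (-0.62) lost their call without background subtraction, and fibroblast genes gained one with an offset of 10 (0.060, limma adjusted p = 0.0402) and with spike-in scaling (0.000899). Camera compares a list with other genes, all lowered by the same amount in spike-in scaling. The fibroblast call with that scaling therefore does not follow from the median of -0.65, and is not evidence of matrix genes higher in astrocytes.

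With an estimated correlation, camera kept the medians and lost the calls of the myelin (2.57), precursor (0.95), astrocyte (-2.13), reactive (-1.63), microglia (1.39), neuron (0.75), serum response (-0.76), cholesterol (0.84), BMP and Notch (-0.62), ependymal (-2.87) and interferon (-0.49) lists, with limma adjusted p from 0.285 to 0.496. With 1 residual degree of freedom this form of camera had little power, so these losses do not show an effect of gene correlation. Either array alone gives values with no test: 1319 to 1443 genes at least 2-fold higher in oligodendrocytes and 1802 to 2046 in astrocytes. The medians on 1 array ran from 1.22 to 1.33 for microglia, 0.082 to 0.16 for fibroblast, -0.070 to 0.14 for PI3K-Akt-mTOR, -0.060 to 0.023 for endothelial and -0.084 to -0.0024 for miR-17~92 target genes, -0.041 to -0.0086 for cell cycle, 0.71 to 0.88 for cholesterol, 0.019 to 0.068 for miRNA biogenesis, -0.54 to -0.47 for BMP and Notch, -0.47 to -0.44 for interferon, 2.54 to 2.69 for myelin and -2.23 to -2.12 for astrocyte genes. Signal over background limits the ratios of dim genes: that of Pdgfra was 0.51 as reported, 0.81 with an offset of 10 and 1.26 with Feature Extraction's log ratio. The planned seed-site test was not run, and the correlation of the arrays stayed between 0.923 and 0.931 under its alternatives.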

Other observations

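The gene lists in this part, and the tests on microglia, were drawn up after the ratios had been seen, in part from genes that headed the ranking, so their directions are not independent evidence; of their members, 1 phagocytic, 7 surveillant, 2 complement, 1 metal-handling, 5 GABAergic and 3 transport genes also stand in the lists above; the expectations for the cilia tests were written before those list medians were seen, though other cilia genes had been seen among the largest ratios. Genes of complement and of protease inhibition were mostly higher in astrocytes: of 16 tested, 11 were higher in astrocytes and 3 in oligodendrocytes, with a median of -2.06. Beside Itih3, Cfi and A2m, C4b stood at -3.10 ± 0.29 and C1ra at -2.69 ± 0.022, while C2 (1.06) and Masp1 (0.94) were higher in oligodendrocytes. Metal-handling genes parted: the metallothioneins Mt2 (-3.49 ± 0.60), Mt1 (-2.35 ± 0.29) and Mt3 (-1.77 ± 0.23), the iron reductase Cybrd1 (-3.44 ± 0.025) and ceruloplasmin Cp (-2.51 ± 0.15) were higher in astrocytes. The transferrin receptor Tfrc (2.17 ± 0.21), the iron exporter Slc40a1 (1.89 ± 0.23) and the ferritins Ftl1 (1.27 ± 0.45) and Fth1 (0.81 ± 0.28) were higher in oligodendrocytes. Microglia genes, with a median of 1.39, were also higher on that side. Adjusted over the list alone, 14 complement and 10 metal-handling genes were called; limma's camera gave adjusted p = 0.000213 and 0.218, and adjusted p = 0.348 and 0.433 with an estimated correlation.

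Of 12 melanocyte genes listed, 8 were tested, and 4 of these were higher in oligodendrocytes. Beside Dct these were Mitf (1.80 ± 0.13), Kit (1.12 ± 0.090) and Pmel (0.93 ± 0.27). Rab27a (-0.49 ± 0.055) was higher in astrocytes, while Oca2 (0.13), Slc45a2 (0.15) and Gpr143 (0.076) were not called. Of 13 genes of GABAergic neurons, 8 were higher in oligodendrocyte cultures, 3 were higher in astrocytes and 2 were not called. The peptides Sst (1.89 ± 0.079) and Npy (1.75 ± 0.091) were among the former, and Pvalb (-2.23 ± 0.18) was among those higher in astrocytes. A list of genes linked to glutamate and GABA transport differed by member. The glutamate transporter Slc1a1 and the cystine exchanger Slc7a11 (1.10 ± 0.16) were higher in oligodendrocytes. Slc1a2 (-3.17 ± 0.24) and the glutamine transporter Slc38a3 (-2.18 ± 0.029) were higher in astrocytes. Of these 8, 13 and 12 genes, 5, 11 and 10 were called when adjusted over the list alone; limma's camera gave adjusted p = 0.0104, 0.0328 and 0.121, and adjusted p = 0.376, 0.433 and 0.433 with an estimated correlation.

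Microglia genes read higher in the oligodendrocyte cultures, and per the labels microglia were shaken off the astrocyte cultures before harvest. More of the same microglia would shift the genes that they alone make alike; the SD over 31 brighter members was 0.65, against a median standard error of 0.128. Probes of one gene also differed, with an SD of 0.397 over the 15 members with several probes, and of 0.191 over bright probes of 9 members. The first value includes dim probes, whose ratios the offset pulls toward 0: Ptprc read from 0.40 on its dimmest probe to 2.12 on its brightest. Counting the dim probes, a larger share of one unchanged population may still account for the pattern and is left open. A more phagocytic state may also play a part: phagocytic genes such as Lpl (3.61 ± 0.62), Mmp12 (3.25 ± 0.27) and Gpnmb (3.23 ± 0.052), of which 13 of 19 were higher in oligodendrocyte cultures and 4 lower, had a median 0.84 above that of surveillant genes, of which 10 of 14 were. The 2-sided permutation p over genes was 0.14077, which leaves it open, and other cell types that make some of these genes were not tested.

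Ependymal cilia genes read higher in the astrocyte cultures. Cells with motile cilia among the astrocytes may account for this: 29 further motile cilium genes had a median of -2.62, and 29 of them were called higher in astrocytes. Intraflagellar transport genes, which all cilia use, had a median of -1.44 with 28 of 29 called. This median was closer to 0 than that of the ependymal list by 1.42 (2-sided permutation p over genes = 1e-05, the smallest that 100000 permutations can give). Genes of a list are not independent, and any expression of transport genes outside motile cilia in both cultures would also draw their ratio toward 0. The difference therefore cannot decide whether there were more cilia of every kind. Whether such cells are ependymal cells or astrocytes that express these genes was not tested, and Ttr stood on the other side at 2.09.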
